A study of Candida albicans with 4 samples.

How the data were processed

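Relative transcript levels were taken from 4 two-colour spotted arrays of *Candida albicans*. Per the labels' protocols, aminoallyl cDNA was made from total RNA, coupled to Cy3 or Cy5 and hybridised in a direct design with balanced dye swaps and no reference sample. Histatin 5-treated CAI-4 RNA was in Cy5 and untreated CAI-4 RNA in Cy3 on 2 arrays, and the dyes were swapped on the other 2 arrays. Each orientation has replicates 1 and 2, numbered from the titles, where a title without a number was taken as replicate 1. The labels speak of duplicate experiments and dye-swap replicates but do not say which arrays share cultures or RNA extracts, so the p-values measure only the spread between these arrays, which may be technical.

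The deposited value table holds signed log ratios for 14112 spots, taken here as log2. The log base, the dye in the numerator, the background correction, the normalization and the filter behind missing values are not given in the sources used here. A base of 10 was ruled out by the range of the values, and base 2 is the convention. Each deposited column was already centred near 0: the medians were −0.0056 and −0.0089 for replicates 1 and 2 with histatin 5 in Cy5, and 0.013 and 0.012 for replicates 1 and 2 with histatin 5 in Cy3. Over all spot pairs, deposited values of arrays with swapped dyes correlated at −0.83 to −0.57 (Pearson) and −0.38 to −0.11 (Spearman), and those of one orientation at 0.69 to 0.79 (Pearson). By the rule fixed in advance the values were therefore read as a ratio of one dye to the other, and the arrays with histatin 5 in Cy3 were turned in sign. The large Pearson values rest mostly on the regularly spaced positions described below. Over genes alone, after turning, pairs with swapped dyes correlated at −0.076 to 0.28 (Pearson) and 0.056 to 0.33 (Spearman), so the genes themselves bear on this reading only weakly. Which dye is the numerator stays unknown. The turned values are treated over untreated if the deposited ratio is Cy5 over Cy3, and the opposite if it is Cy3 over Cy5. The rule does not exclude that the values were deposited already as treated over untreated. A dye bias could then give the same signs of correlation, and the treatment and dye terms would change places. Intensities were not analysed here, so no spot was filtered on its brightness. Values were present for 88.0%, 92.4%, 93.9% and 89.5% of spots in the same order of arrays.

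Duplicate spots lie 7056 positions apart and were averaged. Their values correlated within arrays at 0.60 to 0.72, and the SD of a single spot about its duplicate was 0.12 to 0.17 on the log2 scale. In each of 16 blocks of 441 positions per duplicate, the positions that are a multiple of 24, and position 437, held the ratios of at least 2-fold mean size. Of these 304 regularly spaced positions, 220 had a value on all 4 arrays and 105 reached that size, while the others did not. None carried an annotated gene, where 14.8 annotated pairs were to be expected. As a class they were treated as control spots and left out together with 64 empty positions, a decision made after the values were seen. Arrays were centred on the median of the other 6688 spot pairs. The platform annotation gave 680 spots, or 340 spot pairs, 1 gene symbol each, and the other 13432 spots none. There were 300 symbols, of which 7 were updated through the gene identifier. FET3, UPC2, ERG24 and CAM1-1 are listed there as FET33, ECM22, ERG4 and CAM1. Spot pairs of one symbol were averaged. Of 30 genes with several measured pairs, the pairs of 15 differed in sign, with a median range of 0.16 on the log2 scale. Genes measured on all 4 arrays were tested, 6422 in all, of which 6129 are single spot pairs without a symbol, and 226 with a missing array were left out.

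The tests, gene lists, naming rule and first set of alternatives were fixed before the data were examined. Turned log2 ratios were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with a treatment coefficient tested against 0 and a dye term, which leaves 2 residual degrees of freedom and had a prior of 4.26. The Benjamini-Hochberg threshold was 0.05. Camera, with a preset correlation of 0.01, was run on the 16 of 22 gene lists with at least 3 measured members against the genes with a symbol. The lists cover osmotic stress and glycerol, oxidative stress, heat shock and chaperones, glycolysis and fermentation, gluconeogenesis with glyoxylate and fatty acid oxidation, the tricarboxylic acid cycle and respiration, cytosolic ribosomal proteins, ribosome biogenesis, translation factors, cell wall and adhesins, hyphal genes, ergosterol, efflux, histatin 5 uptake and resistance, iron and copper, amino acid biosynthesis, nitrogen and amino acid uptake, phosphate, trehalose and glycogen, the proteasome, vacuolar and plasma membrane ATPases, and histones. Together they held 99 measured genes.

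Genes past the threshold with one sign on all arrays were to be named by size and by list, together with some genes named in advance. With fewer than 10 genes past it, the rule was to name the 10 genes with the smallest p, with their values and no verb of change. It was applied to genes with a symbol. Further members of lists and spots without a name were chosen after their values were seen. Errors are SDs over 4 turned arrays.

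The fit was tested on simulated data for this comparison, with 200 of 6422 genes changed at the measured spread. It recovered 80% of changes of 0.5 on the log2 scale and 100% of changes of 1, 2 and 3, with 7 false calls. The simulation held 50 changed genes at each size, and large changes ease the adjusted threshold for small ones. In the measured data 12 genes reached a mean of 1.5-fold, 0 reached 2-fold, and 0 passed. The recovery therefore does not tell how many changes of 0.5 to 1 were missed here. Alternatives were the dye term, averaging of arrays with one number, a replicate block, leaving out each array, centring and scaling, missing arrays, spot averaging, robust eBayes, a plain one-sample statistic, fold thresholds, and other settings of camera. Settings added after the data were seen were the regular positions, the adjustment and background genes, a crossed pairing, subtraction of the 6 nearest spots, and further combinations of settings and results. Values with 1 array left out come from the fit with the dye term. The single array remaining in its orientation then weighs as much as the others together, so these values are not plain means of the remaining arrays. Figures were drawn with matplotlib 3.10.9. No gene coordinates are given because the genome build of the probes is not given in the sources used here.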

Results

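The transcriptional response of *Candida albicans*, a yeast that lives on human mucosal surfaces, to histatin 5 was measured on spotted two-colour microarrays. Histatin 5 is a cationic, histidine-rich peptide of human saliva with antifungal activity. Cells of the laboratory strain CAI-4, called wild-type in the labels, were treated with 500 µM histatin 5 for 60 min in 10 mM sodium phosphate buffer at pH 7.4, a dose given as lethal to 40% of cells. They were compared with CAI-4 cells that received no peptide. Each of the 4 arrays carried treated and untreated RNA together, with the treated RNA in Cy5 on 2 arrays and in Cy3 on 2 arrays. The labels describe the buffer wash and incubation for the treated cells alone, so the values compare treated cells in buffer with untreated cells whose handling after growth is not given in the sources used here. Of 14112 spots, 12425 and 13036 had a value on replicates 1 and 2 with histatin 5 in Cy5, and 13247 and 12626 on replicates 1 and 2 with histatin 5 in Cy3. The number of arrays limits the precision, and the spot intensities were not analysed here.

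The first question was which genes differed in transcript level between histatin 5-treated and untreated cells. Among the genes with a symbol, the smallest p belonged to RPP1B, an acidic protein of the ribosomal stalk, whose mean log2 ratio was 0.35 ± 0.064 (SD, n = 4), a 1.28-fold difference. A positive value likely stands for a higher level in treated cells. This reading rests on the usual convention of Cy5 over Cy3, which the labels do not state, and with Cy3 over Cy5 every sign given here turns over. It also takes the deposited values as a ratio of dyes. Had they been deposited already as treated over untreated, the turned means given here would be dye differences. ABZ1, an enzyme on the route to p-aminobenzoate, had a value of similar size on the opposite side (−0.35 ± 0.075, SD, n = 4), as did SPB1, a methyltransferase of ribosome assembly (−0.30 ± 0.096, SD, n = 4), and LYS5, needed for lysine synthesis (−0.29 ± 0.12, SD, n = 4). On the side of RPP1B lay MEC3, a DNA damage checkpoint protein (0.37 ± 0.24), ALK8, a cytochrome P450 (0.35 ± 0.12), FET3, a multicopper oxidase of iron uptake (0.26 ± 0.052), NAG1, glucosamine-6-phosphate deaminase (0.26 ± 0.13), ATP7, a subunit of mitochondrial ATP synthase (0.24 ± 0.085), and ASC1, a protein of the small ribosomal subunit (0.24 ± 0.078; SD, n = 4 for each). Each of these 10 genes had one sign on all 4 arrays after the ratios of the dye-swapped arrays were turned. MEC3 rested in part on Hst5-in-Cy5 replicate 1, where its ratio was 0.72, and its value was 0.24 without that array. The value of SPB1 averages 2 spot pairs, of which 1 had no value on Hst5-in-Cy3 replicate 1. The pairs had −0.27 and −0.53 on Hst5-in-Cy5 replicate 1 and −0.29 and −0.39 on Hst5-in-Cy5 replicate 2. On Hst5-in-Cy3 replicate 2 they had −0.026 and −0.55, so the SD of SPB1 leaves out a spread between pairs. No gene passed the test, and the adjusted p of these 10 genes ran from 0.119 to 0.142 in limma. With same-numbered arrays averaged, a setting described below with its limits, 8 of the 10 passed. With a fixed replicate block 0 of them did.

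**Figure D1:**
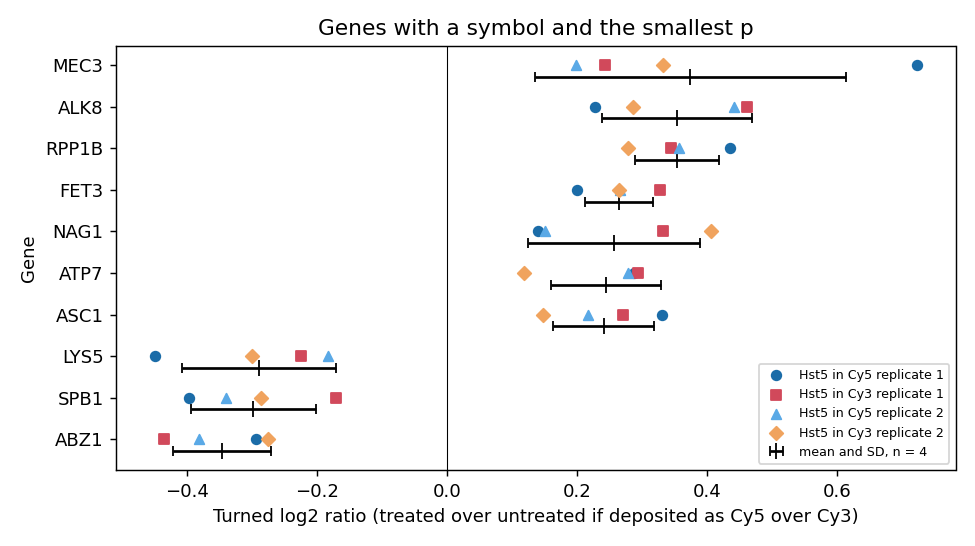
Turned log2 ratios on the 4 arrays for the 10 genes with a symbol and the smallest p. Each symbol is 1 array, and the black line gives the mean and SD (n = 4). RPP1B lies between 0.28 and 0.43 and ABZ1 between −0.44 and −0.28, and none of the 10 genes has arrays on both sides of 0.

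Across 6422 genes, 0 passed a Benjamini-Hochberg adjusted p of 0.05 in limma, and the lowest adjusted p was 0.119. At an unadjusted p under 0.05 there were 1265 genes, 671 on the positive and 594 on the negative side, where 321.1 were to be expected by chance. Without Hst5-in-Cy3 replicate 1 the number was 674. Among the 293 genes with a symbol, 55 had an unadjusted p under 0.05, 37 positive and 18 negative, and 0 passed when the adjustment ran over these genes alone, a setting chosen after the data were seen (lowest adjusted p = 0.148). A plain one-sample t statistic also gave 0 genes after adjustment. The mean ratios were small: the median size was 0.083 on the log2 scale against a median SD of 0.13, 12 genes reached a mean of 1.5-fold and 0 reached 2-fold. The 0 follows in part from leaving out the regularly spaced positions after the values were seen, since 105 of them reached 2-fold. The extreme mean values belonged to spot pairs without a gene name in the annotation. Spots 4843 and 1607 had −0.99 ± 0.66 and −0.91 ± 0.49, and spots 1283 and 4413 had 0.91 ± 0.47 and 0.84 ± 0.51 (SD, n = 4). Whether arrays with the same replicate number share RNA extracts is not stated. With such arrays averaged into 2 samples, 420 genes passed the adjusted threshold, 225 positive and 195 negative, 13 of them with a symbol. This test leans on a prior of 10.1 degrees of freedom. Deviations of same-numbered turned arrays correlated at −0.228, and averaging takes deviations of opposite sign out of the residual spread. A fixed replicate block and a crossed pairing gave 5 genes each. A random block gave 0 with the dye term and 352 without it.

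Of the gene groups, genes for cytosolic ribosomal proteins lay together on the positive side. All 4 measured members had a positive mean, with a median log2 ratio of 0.18, and the list stood apart from the other genes with a symbol (limma camera, adjusted p = 0.0301 over 16 lists). With a correlation estimated for the list this call was lost (adjusted p = 0.947 with an estimated correlation), as it was on ranks (adjusted p = 0.0608). The members were RPP1B, ASC1 (values above), RPL3 with 0.12 ± 0.062 and RPS3 with 0.082 ± 0.15 (SD, n = 4). The sign of RPS3 followed the dye, with 0.22 and 0.19 on the Hst5-in-Cy5 arrays and −0.020 and −0.067 on the Hst5-in-Cy3 arrays. RPP1B, ASC1 and RPL3 were positive on all 4 arrays. RPP1B and ASC1 passed when adjusted over the list alone, and 0 passed over all genes tested. Genes of ribosome biogenesis lay on the opposite side: 12 of 15 measured members had a negative mean, with a median of −0.068 (camera, adjusted p = 0.0301). This call too was lost with an estimated correlation (adjusted p = 0.947 with an estimated correlation) and on ranks (adjusted p = 0.0608). The estimated correlation was 0.034, and the same limit of 2 degrees of freedom holds. SPB1, whose 2 spot pairs differed as given above, was the 1 member that passed when adjusted over the list alone, and 0 passed over all genes. NMD3, an export adapter of the large ribosomal subunit, had −0.18 ± 0.053 and DBP7, an RNA helicase, −0.18 ± 0.099 (SD, n = 4). The biogenesis list's median is the value of DBP2, whose 2 spot pairs differed in sign over a range of 0.22 on the log2 scale. With 1 array left out, UTP20, RPA190, ENP1 and NOP4 turned from negative to positive, and NOP8, RRN3 and RRP42 from positive to negative. The ribosomal protein list also lost its call without Hst5-in-Cy5 replicate 1 (adjusted p = 0.109), without Hst5-in-Cy3 replicate 1 (0.0762) and without Hst5-in-Cy5 replicate 2 (0.0987). The biogenesis list lost it without Hst5-in-Cy5 replicate 1 (0.163) and without Hst5-in-Cy3 replicate 2 (0.0927), against all genes tested as the background (0.105) and with neighbouring spots subtracted (0.0583).

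**Figure D2:**
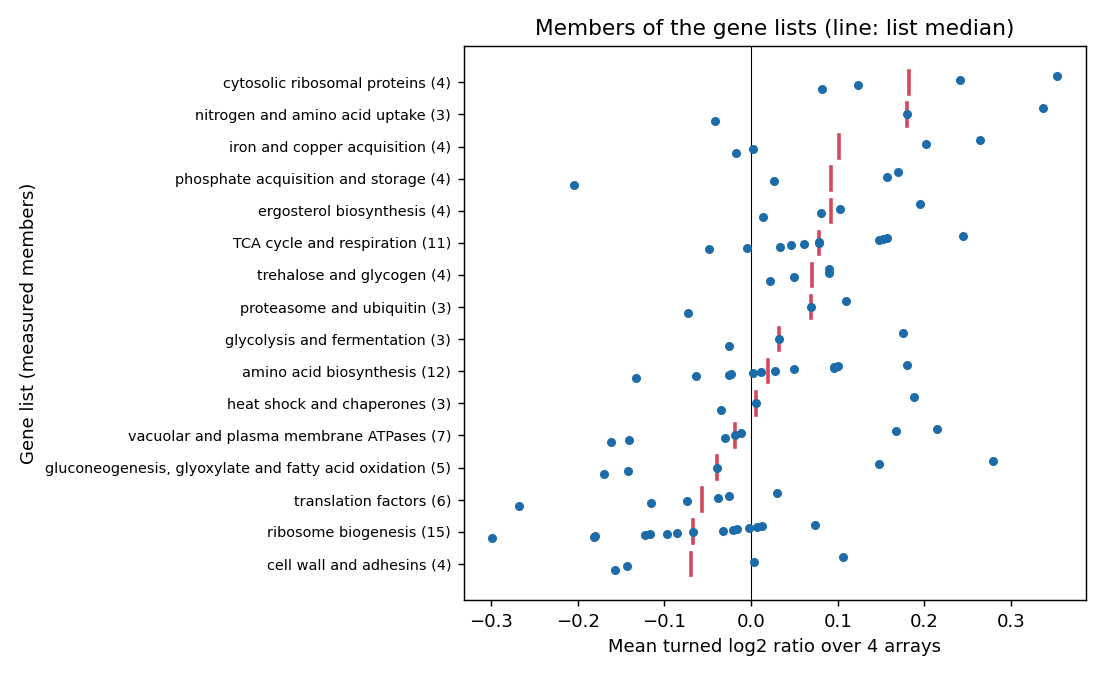
Mean turned log2 ratios over 4 arrays for the members of the 16 gene lists with at least 3 measured members. Each point is 1 gene, the red line is the list's median, and the number of measured members stands in parentheses. All 4 genes for cytosolic ribosomal proteins lie above 0, and 12 of the 15 genes of ribosome biogenesis lie below 0.

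None of the other 14 lists passed, and 0 of their members passed over all genes tested. Of 11 genes of the tricarboxylic acid cycle and respiration, 9 had a positive mean and the list's median was 0.078 (camera, adjusted p = 0.271). ATP7 (value above), the succinate dehydrogenase subunit gene SDH4 (0.16 ± 0.20), the ATP synthase gene ATP1 (0.15 ± 0.12) and the succinyl-CoA ligase gene LSC2 (0.15 ± 0.25) had its 4 highest values (SD, n = 4). The value of LSC2 averages 2 spot pairs of one sign that differed by 0.18. The sign of this average followed the dye, with 0.32 and 0.40 on the Hst5-in-Cy5 arrays and −0.12 and −0.013 on the Hst5-in-Cy3 arrays. The pair at spot 1439 was positive on all 4 arrays, and the sign of the pair at spot 3957 followed the dye. ATP7, SDH4 and ATP1 were positive on all 4 arrays. SDH4 was 0.072 without Hst5-in-Cy5 replicate 1, and ATP1 was 0.087 without Hst5-in-Cy5 replicate 2. Without Hst5-in-Cy5 replicate 2 the list's median was 0.048, the value of QCR2. In the iron and copper list, FET3 and its relative FET31 (0.20 ± 0.14, SD, n = 4) passed when adjusted over the list alone, while CTR1, a copper transporter, and YFH1, frataxin, had 0.0018 ± 0.11 and −0.017 ± 0.071 (SD, n = 4). With 1 array left out, CTR1 ran from −0.023 to 0.027 and YFH1 from −0.044 to 0.010. The list of 4 genes did not stand apart (adjusted p = 0.433). Translation factors (5 of 6 negative) and nitrogen and amino acid uptake (2 of 3 positive) also had an adjusted p of 0.433. In the uptake list the permease gene CAN3 had 0.34 ± 0.48 and the amine oxidase gene AMO2 0.18 ± 0.11 (SD, n = 4). CAN3 ran from 0.15 without Hst5-in-Cy5 replicate 2 to 0.52 without Hst5-in-Cy5 replicate 1, and AMO2 was 0.12 without Hst5-in-Cy3 replicate 1. All 4 measured genes of ergosterol biosynthesis had positive means, with ERG10 highest at 0.20 ± 0.15 (SD, n = 4; 0.12 without Hst5-in-Cy5 replicate 1; list adjusted p = 0.522), as had all 4 genes of trehalose and glycogen (adjusted p = 0.742). ERG1 and ERG24 were −0.039 and −0.079 without Hst5-in-Cy3 replicate 1, and −0.0058 and −0.042 without Hst5-in-Cy5 replicate 2. TPS1 was −0.068 without Hst5-in-Cy5 replicate 2, and UGP1 was −0.030 without Hst5-in-Cy5 replicate 1. Cell wall and adhesin genes were split, 2 positive and 2 negative (adjusted p = 0.742). The remaining 7 lists were heat shock and chaperones, glycolysis and fermentation, gluconeogenesis with fatty acid oxidation, amino acid biosynthesis, phosphate, proteasome, and the vacuolar and plasma membrane ATPases. Each of these had an adjusted p of 0.913. Median, mean and test differed in sign for gluconeogenesis with fatty acid oxidation (median −0.039, mean 0.015, test negative) and for the ATPase list (median −0.019, mean 0.0029, test negative). The measured members of the ATPase list were CMD1, MID1, STV1, VCX1, VMA2, VMA22 and VPH1. The plasma membrane ATPase gene PMA1 was not among them. Glycolysis and fermentation, with 2 of 3 members positive, passed without Hst5-in-Cy5 replicate 2 (camera, adjusted p = 0.0393). ENO1 and PGK1 had 0.52 and 0.46 in that fit, against 0.032 and 0.18 with all arrays, and GLK4 had −0.10. Hst5-in-Cy5 replicate 1 was then the single array of its orientation, with 0.95 for PGK1 against −0.30 on Hst5-in-Cy3 replicate 1. The translation factors passed without Hst5-in-Cy3 replicate 2 (adjusted p = 0.0421).

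The other 6 lists had fewer than 3 measured members and were not tested. The osmotic stress list was represented by the sodium-proton antiporter gene CNH1 (0.084 ± 0.013) and the glycerol kinase gene GUT1 (0.13 ± 0.26), and the oxidative stress list by GLR1, glutathione reductase (−0.057 ± 0.091), and MCR1 (0.051 ± 0.13; SD, n = 4 for each). ECE1 and PCL1 of the hyphal list had 0.0037 ± 0.072 and −0.12 ± 0.052, the efflux gene NAG4 had 0.15 ± 0.079, and the centromeric histone gene CSE4 had −0.059 ± 0.14 (SD, n = 4). The values of CNH1 and PCL1 average 2 and 4 spot pairs whose means differed in sign, over a range of 0.20 and 0.21 on the log2 scale, so their small SDs leave out a spread between pairs larger than the mean itself. The 2 pairs of NAG4 had one sign and differed by 0.13. The values of GUT1, GLR1, MCR1, ECE1 and CSE4, whose SD exceeded the mean, moved by over 1.5 times or changed sign with 1 array left out. None of the genes of these lists passed over its list alone or over all genes tested. The genes with known roles in histatin 5 uptake, binding or resistance, and RHR2, SKO1, HSP70, CTA1, PDC11 and HOG1, were not analysed here because no spot carries their symbol in the annotation used.

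The dye swap let the ratio of each gene be compared between the orientations. Across genes, which are not independent replicates, Pearson's r between pairs of turned arrays ran from −0.076 to 0.44, with a mean of 0.22. The lowest value was that of the replicate 1 arrays of opposite dye. The same sign on all 4 turned arrays was found for 1841 genes (28.7%), where unrelated signs would give 12.5%. A dye effect passed an adjusted p of 0.05 for 2 genes and an unadjusted p under 0.05 for 537. The 2 genes, at spots 6152 and 848, are unnamed in the annotation, and their dye coefficients were 1.13 and 1.04 on the log2 scale (limma, adjusted p = 0.0040 and 0.0065). Without Hst5-in-Cy3 replicate 1 or Hst5-in-Cy3 replicate 2 the number was 0, and without Hst5-in-Cy5 replicate 2 it was 8.

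Large ratios were found at many of the regularly spaced positions of the array that carry no annotated gene and were left out as control spots. Of 220 such positions with a value on all 4 arrays, 105 had a mean ratio of at least 2-fold, against 0 of the 6456 other spot pairs. The class was drawn after the values were seen, from where such ratios lay, so the 0 follows in part from that choice. With these positions included, the mean correlation between turned arrays was 0.71 and 99 items passed an adjusted p of 0.05, of which 85 were such positions, 14 lay elsewhere and 0 had a symbol.

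**Figure D3:**
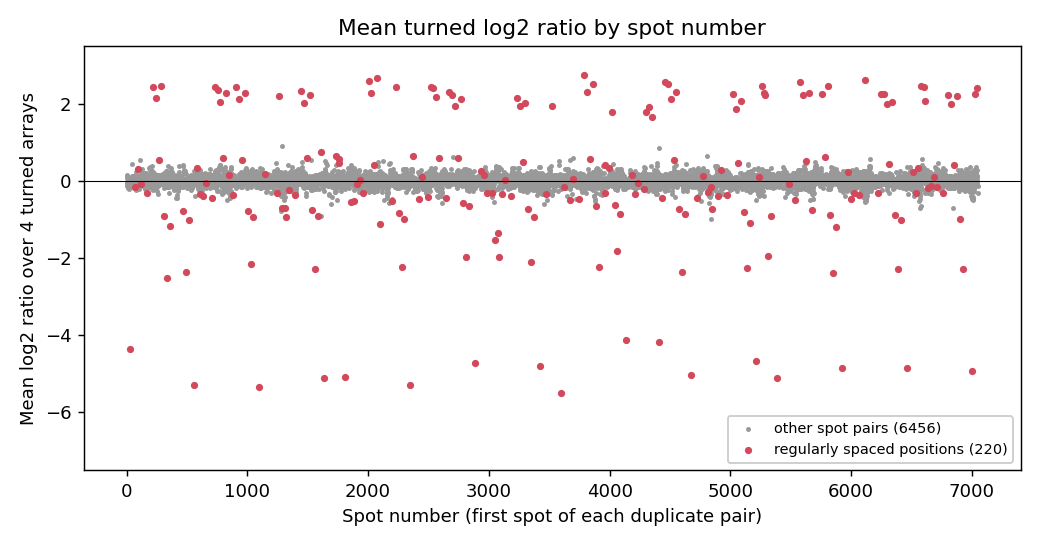
Mean turned log2 ratio over 4 arrays for each duplicate spot pair, against the number of its first spot. The 220 regularly spaced positions (red) reach from −5.49 to 2.76, and none of the 6456 other pairs (grey) reaches a size of 1.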

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

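The tests of control RNAs, of a dye artefact at the regular positions and of a dye bias shared by arrays of one number were chosen after the values were seen. The tests of neighbouring spots and of other sign patterns were written before their results were seen.

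A strong signal appeared in spots outside the comparison of genes. Of 220 regularly spaced positions with a value on all 4 arrays, 105 had a mean ratio of at least 2-fold, 64 positive and 41 negative, between −5.49 and 2.76 on the log2 scale, against 0 of 6456 other spot pairs. Since these positions were chosen by where such ratios lay, the 0 follows in part from that choice. If the deposited values are a ratio of one dye to the other, a dye artefact tied to the spot would keep its sign under the swap. Of the 152 positions picked on the Hst5-in-Cy5 arrays, 99.3% had the opposite deposited sign on the swapped arrays. That reading of the values was itself drawn mostly from these positions, so the test cannot exclude a dye artefact. A candidate explanation is control RNA added in unequal amounts to the treated and untreated samples: ratios at positions 23 apart in the series of regular positions correlated at 0.66, with 0.28 at the next highest lag. That is below the bound of 0.7 set for this explanation, and no label names control spots, so it cannot be told apart from another content of these positions. A response of yeast genes printed there was not tested, since no annotated gene lies at these positions.

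The second pattern is a weak shift over many genes, with 1265 genes at an unadjusted p under 0.05 and 0 past the adjusted threshold in limma. Without Hst5-in-Cy3 replicate 1 the 1265 became 674, and with same-numbered arrays averaged the 0 became 420. With a fixed replicate block or the crossed pairing the 0 became 5. With a random block it stayed 0 with the dye term and became 352 without it. The values argue against a trend shared by neighbouring spots as the whole cause of this pattern. After subtraction of the 6 nearest spots the mean correlation between turned arrays was 0.175, with a bootstrap SD of 0.011, against 0.221 before. That SD does not measure the spread between arrays, whose pairs ran from −0.076 to 0.44 before subtraction. After it, 1032 genes had an unadjusted p under 0.05 in limma. A dye bias shared by arrays of one number may widen the spread of genes, since deviations of the deposited values correlated at 0.228 between such arrays. Without the dye term, 1 of the 8 sign patterns of the 4 arrays, the treatment pattern itself, gave as many as 1196 genes at an unadjusted p under 0.05, with 395 for the highest other pattern, and 8 patterns are too few for a share under 0.05. An effect of histatin 5, and one of the buffer incubation described for treated cells alone, stay open as explanations that the design does not separate. A dye bias over many genes stays open too, if the values were deposited already as treated over untreated.

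The ratio of 2 genes, at spots 6152 and 848, differed between the dye orientations by the test of the dye term (adjusted p = 0.0040 and 0.0065). The number was 0 without either Hst5-in-Cy3 array and 8 without Hst5-in-Cy5 replicate 2.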

How the results depend on the processing

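Settings chosen after the data were seen are the regular positions, the crossed pairing, the neighbour subtraction, the all-gene background, the adjustment over genes with a symbol, both random blocks, the leave-out fits of the dye effect, and for the gene lists the scaling settings and the block. The count of 0 genes past the adjusted threshold became 420 with arrays of one number averaged, 1 with genes measured on at least 3 arrays and 99 with the regular positions included, 85 of them at such positions. Averaging removes deviations of opposite sign within a number from the residual spread. The cause of the other shifts was not tested. With the replicate number as a fixed block the count was 5, and the deviations of same-numbered turned arrays correlated at −0.228. The crossed pairing gave 5 genes as well, since in this design it leaves the same residual contrast. The planned random block was not run with duplicateCorrelation, which skips genes with 4 arrays and a dye term. With the correlation of the random replicate block taken from the residual contrasts instead (−0.12), the count was 0. With duplicateCorrelation and no dye term (−0.36), it was 352. The count was 0 under each other setting, and under each left-out array, where 674 to 1142 genes had an unadjusted p under 0.05. Of 200 values of the 10 named genes under alternatives, 182 kept their side of the threshold, 18 passed it, 8 under averaging and 10 with the random block and no dye term, and 0 changed sign. Since these 10 genes had one sign on all 4 arrays, leaving out or averaging arrays could not change it. Settings that alter only the test, such as the dye term, the blocks and the adjustment, left the values themselves unchanged. That 0 changed sign was thus in large part fixed in advance. The dye effect gave 0 to 8 genes with 1 array left out. The mean correlation between arrays was 0.711 with the regular positions. The number of lists past the threshold was 0 with an estimated correlation (adjusted p = 0.947 for both lists), 0 on ranks (0.0608 for both), 1 with the all-gene background (ribosome biogenesis 0.105), 1 with neighbours subtracted (ribosome biogenesis 0.0583), and 0 to 2 with 1 array left out. Over the left-out arrays the adjusted p ran from 0.0421 to 0.109 for cytosolic ribosomal proteins and from 0.0393 to 0.163 for ribosome biogenesis. The setting with an estimated correlation tests on the 2 residual degrees of freedom, which leaves it little power over 16 lists. Cytosolic ribosomal proteins and ribosome biogenesis kept their direction under each setting tried, which was not tabulated for the other lists. No scaling moved the median of all genes by 0.1. The limits set by signal over background are unknown because intensities were not analysed here.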

Other observations

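The genes described here were chosen after their values were seen. With arrays of one number averaged, the 13 genes with a symbol past the adjusted threshold comprised 8 of the 10 named above and 5 others. SPF1, a P-type ATPase of the secretory pathway, had a mean log2 ratio of 0.33 ± 0.35, VPS33, a protein of vacuolar sorting, 0.30 ± 0.32, the permease CAN3 0.34 ± 0.48, the aldehyde dehydrogenase ALD6 0.28 ± 0.23 and the elongation factor TEF2 −0.27 ± 0.73 (SD, n = 4). Each of these 5 had both signs among the 4 turned arrays, and 349 of the 420 genes had 1 sign. With 1 array left out of the fit with the dye term, each of the 5 moved by over 1.5 times. Without Hst5-in-Cy5 replicate 2 ALD6 was 0.18, CAN3 0.15 and TEF2 0.066. VPS33 was 0.15 without Hst5-in-Cy5 replicate 1, and SPF1 was 0.22 without Hst5-in-Cy3 replicate 2. These are not plain means of the remaining arrays, because the single array of its orientation weighs as much as the others together. Part of each move can come from that weighting. The fitted values of ENO1, YHB1, HEM13 and ICL1, given next, changed sign with 1 array left out.

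The SD across arrays was highest, among genes with a symbol, for ENO1, the glycolytic enolase (0.032 ± 1.02), YHB1, a flavohemoglobin that detoxifies nitric oxide (0.024 ± 0.92), TEF2, HEM13, coproporphyrinogen oxidase (0.10 ± 0.71), and ICL1, isocitrate lyase (−0.039 ± 0.70; SD, n = 4). In ENO1 the turned ratio was 1.47 on Hst5-in-Cy5 replicate 1 and −0.86 on Hst5-in-Cy3 replicate 1, and in YHB1 it was 1.11 and −1.13, so that on these arrays the sign followed the dye. On the Hst5-in-Cy5 and Hst5-in-Cy3 arrays of replicate 2, YHB1 had 0.22 and −0.11, while ENO1 had −0.48 and −0.00054, where its sign did not follow the dye.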
